A study of Mus musculus with 16 samples.

How the data were processed

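The series holds 16 RNA libraries from mouse placenta: foetal placenta at embryonic day (E) 13.5 and labyrinth at E18.5, each from animals labelled wild type (WT), Mbnl2 knockout (Mbnl2 KO), Mbnl3 knockout (Mbnl3 KO) and knockout of both (DKO), with 2 replicates per group. Per the labels, total RNA was taken with a column kit and made into QuantSeq REV libraries, which read the 3' ends of polyadenylated transcripts. Genome build mm10 is named per the submitters' processing notes. The aligner, the counting tool, the annotation, the strand setting and the handling of reads shared between genes are not given in the sources used here.

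Each deposited file gives, for 36902 Ensembl genes, a raw count of reads and a corrected RPKM (cRPKM) made by the authors. The deposited RPKM column was the count divided by a length fixed for each gene and by a depth per library. Checked on 609 genes with high counts, that depth equalled the library's count total with a spread of 0.019% between genes. In every file 3342 genes were given as NA and were left out, which left 33560 genes with a deposited count. Symbols and positions came from GENCODE M21 by Ensembl identifier, and 33371 genes matched. The 189 genes without a match held at most 0.018% of any library's counts, and 24 genes shared a symbol with another gene.

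Count totals ran from 4913355 to 10423582 per library. A count of 3, used as the detection floor, corresponded to 0.288 to 0.611 CPM (reads of a gene per megaread of the library) depending on the library. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

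The main test was edgeR's quasi-likelihood F test on the raw counts, in 1 fit of all 16 libraries with a mean for each of the 8 groups. Libraries were scaled by the trimmed mean of M values (TMM), and filterByExpr with a minimum count of 10 kept 12710 genes. The fit had 8 residual degrees of freedom, a prior of 11.5 degrees of freedom and a common dispersion of 0.0223, a biological coefficient of variation of 14.9%. P-values were adjusted by the Benjamini-Hochberg (BH) method within each comparison, and a gene was called changed at an adjusted p under 0.05. The 16 comparisons were each genotype against WT in each tissue, DKO against each KO, the departure of DKO from the sum of both losses, the difference of each effect between tissues, and the stages in WT. Values per group are mean normalised CPM with the SD over 2 libraries, and standard errors of log2 changes are the change divided by the square root of F. No test between groups of 2 libraries could reach a small p by permutation, so all p-values rest on the spread pooled across groups and genes.

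Gene lists for 30 cell types and pathways were written before the data were examined, and the 29 with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists. The lists covered the Mbnl family, syncytiotrophoblast layers I and II, sinusoidal giant cells, labyrinth progenitors, spongiotrophoblast, glycogen trophoblast, parietal giant cells, maternal decidua and uterine NK cells, foetal endothelium, mesenchyme and pericytes, erythroid cells, macrophages, neutrophils and platelets, yolk sac endoderm, sex-linked genes, nutrient transporters, imprinted genes, cell division, DNA replication, cholesterol synthesis, hypoxia and glycolysis, interferon response, unfolded protein response, immediate early genes, oxidative phosphorylation, splicing regulators, polyadenylation factors, insulin-like growth factor signalling and steroid hormone synthesis. Camera was repeated with a correlation estimated from the data, and limma's fry tested whether a list moved on balance in either direction.

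The named genes followed a fixed rule. Mbnl1, Mbnl2 and Mbnl3 are given throughout. Among called genes with a mean of at least 5 CPM in either group and with both libraries of a group beyond both of the other, the 12 largest rises and falls were eligible, or the 5 largest each way for effects built from more than 2 groups, where the library criterion was not used. Where fewer than 5 genes passed, the 5 with the smallest p are given as values. Up to 4 members per gene list called over the list alone are given, or else 2 as values. Predicted genes and pseudogenes were passed over.

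The alternatives were DESeq2's size factors (RLE) in edgeR, no low-count filter, a minimum of 5 CPM, a replicate block, a fit per tissue, DESeq2's Wald test, limma's trend method on log2 cRPKM with a pseudocount of 1 or 0.1, and each library left out in turn, where the lone library of a group was assumed to vary like the other groups. Concordance between comparisons was measured across genes, which are not independent replicates. Because single KO and DKO share WT controls, the covariance of their effects was also measured on 50 simulated data sets without a genotype effect. These were drawn with each gene's spread pooled over all groups. Tested on simulated counts shaped like the E18.5 DKO and WT groups, edgeR called 6%, 38%, 72% and 82% of 50 genes each at true log2 changes of 0.5, 1, 1.5 and 2, and 10 unchanged genes made up 9.2% of its calls. The other 5 genotype comparisons of that simulation, in which nothing was changed, gave 0 calls. Every group was drawn with the same spread per gene, so false or missed calls from unequal spread between groups could not show. A list of 15 genes raised by a log2 of 1 was found by camera at both correlations (adjusted p of 2.08e-21 and 0.000179), with 0 of 28 unchanged lists called. The simulated genes were drawn independently, so this check cannot show false list calls that come from correlated genes. In the data the estimated correlation was 0.608 for erythroid cells and 0.456 for spongiotrophoblast.

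Splicing and the use of alternative polyadenylation sites were not analysed, since the files hold sums per gene. The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.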

Results

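The study measured 3' end counts of polyadenylated RNA in foetal placenta at E13.5 and in the labyrinth, the exchange zone of the placenta, at E18.5. Each tissue was taken from mice labelled WT, Mbnl2 KO, Mbnl3 KO and DKO, a knockout of both Mbnl2 and Mbnl3, which encode RNA-binding proteins of the muscleblind family that regulate splicing and polyadenylation. Each of the 8 groups had 2 libraries. The E13.5 libraries held 5290108 and 8295480 counts in WT, 8936056 and 7639487 in Mbnl2 KO, 7479036 and 9480544 in Mbnl3 KO, and 10156151 and 5037901 in DKO. At E18.5 the totals were 10423582 and 7188053 in WT, 7691635 and 9447684 in Mbnl2 KO, 5523206 and 4913355 in Mbnl3 KO, and 6839554 and 7358083 in DKO. The labels do not say that the replicates are separate animals, so p-values measure only the spread between these libraries, which may be technical.

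Tpbpa, a spongiotrophoblast product, was the most abundant gene in each E13.5 library, and the prolactin relative Prl3b1 or the placental cathepsin Ctsj was the most abundant in each E18.5 library. The first principal component held 66.9% of the variance and separated the tissues, the second held 7.2% and the third 4.8%. On the second component replicates 1 and 2 lay at 7.6 and -28.3 in E13.5 DKO, at -2.9 and -36.8 in E18.5 Mbnl3 KO and at 30.4 and 4.3 in E18.5 Mbnl2 KO. On the third, E13.5 DKO replicate 2 lay at 30.5 and replicate 1 at 2.7. Both replicates of every group differed by more than sampling noise, with a chi-square per gene from 2.76 in E13.5 WT to 24.03 in E13.5 DKO. Xist, transcribed from the inactive X, and the Y-linked Ddx3y were counted in all 16 libraries, at 48.7 to 149 CPM and 11.9 to 36.2 CPM.

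The targeted genes were measured first. Mbnl3 (ENSMUSG00000036109, chromosome X, 51117269 to 51206532) had 83.2 CPM (SD 5.79, n = 2) in E13.5 WT and 1.33 CPM (SD 0.471, n = 2) in Mbnl3 KO, a log2 change of -5.99 (SE 0.31, adjusted p = 5.76e-10 by edgeR's quasi-likelihood test with BH). In the E13.5 DKO it fell to 0.931 CPM (SD 0.378, log2 change -6.33, SE 0.33, adjusted p = 6.48e-10). In the E18.5 labyrinth it fell from 84.3 CPM (SD 11.1) to 2.17 CPM (SD 1.58) in Mbnl3 KO and to 1.3 CPM (SD 0.625) in DKO, with adjusted p of 4.99e-09 and 7.1e-10. Mbnl3 in the Mbnl2 KO groups was 84.9 CPM (SD 5.91) and 84.6 CPM (SD 6.26), not called in either tissue (adjusted p = 1 and 0.995). Mbnl2 (ENSMUSG00000022139, chromosome 14, 120275669 to 120431697) was not called lower in the libraries labelled Mbnl2 KO. It had 386 CPM (SD 8.31) in WT and 410 CPM (SD 14.5) in Mbnl2 KO at E13.5, and 329 CPM (SD 49.6) and 312 CPM (SD 48.8) at E18.5, with log2 changes of 0.09 (SE 0.20, adjusted p = 1) and -0.08 (SE 0.20, adjusted p = 0.891). In DKO it had 492 CPM (SD 118) at E13.5 and 332 CPM (SD 28) at E18.5 (adjusted p = 0.775 and 0.981 against WT). Which part of Mbnl2 was deleted is not given in the sources used here, and a 3' count says nothing about exons that lie outside the counted end. Mbnl2 loss below therefore names a contrast of labels and not a measured fall of Mbnl2. Mbnl1 (ENSMUSG00000027763, chromosome 3, 60472830 to 60629750) had group means of 18.9 to 34.9 CPM and was called in none of the 16 comparisons.

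**Figure D1:**
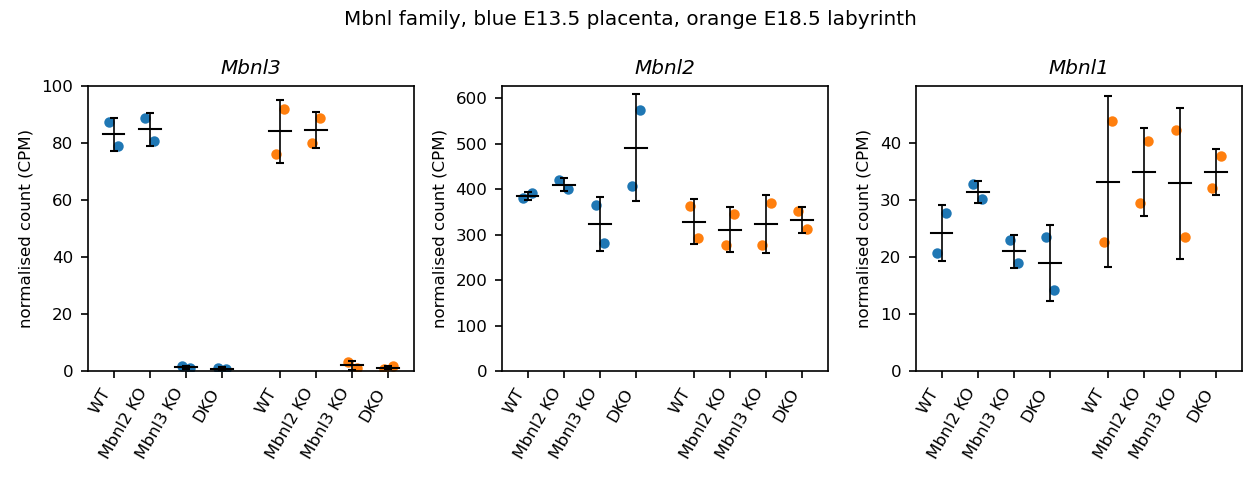
Normalised counts (CPM, linear axis) of Mbnl3, Mbnl2 and Mbnl1 in each library (points) by genotype, with the group mean and SD (bars, n = 2), E13.5 placenta in blue and E18.5 labyrinth in orange. Mbnl3 lies at 83.2 to 84.9 CPM in the WT and Mbnl2 KO groups and at 0.931 to 2.17 CPM in the Mbnl3 KO and DKO groups, while Mbnl2 lies at 312 to 492 CPM in all 8 groups.

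DKO was compared with WT in the E18.5 labyrinth to find which transcripts differed between these labels. Drd4, a dopamine receptor gene (ENSMUSG00000025496, chromosome 7, 141292006 to 141296464), rose from 3.21 CPM (SD 1.17, n = 2) to 35.1 CPM (SD 0.941, n = 2), a log2 change of 3.41 (SE 0.26, adjusted p = 2.42e-07 by edgeR's quasi-likelihood test). The oestrogen sulphotransferase gene Sult1e1 rose by 2.98 (SE 0.32, adjusted p = 1.34e-05), and Plac8, a placenta-enriched gene (ENSMUSG00000029322, chromosome 5, 100553725 to 100572245), rose from 80.7 CPM (SD 6.49) to 468 CPM (SD 13.6), with adjusted p = 9.81e-06. Tnnc1, which encodes a troponin of slow muscle (ENSMUSG00000091898, chromosome 14, 31208312 to 31211729), fell from 24.3 CPM (SD 1.88) to 1.7 CPM (SD 1.19), a log2 change of -3.81 (SE 0.39, adjusted p = 9.06e-06). Corin, the protease that activates natriuretic peptide (ENSMUSG00000005220, chromosome 5, 72300025 to 72504473), fell from 21.5 CPM (SD 4.19) to 2.09 CPM (SD 0.489), with adjusted p = 4.96e-05. The transcription factor genes Esrrb and Pou2f3 rose by 2.62 (SE 0.36) and 2.23 (SE 0.31), the potassium channel gene Kcnj5 by 2.62 (SE 0.37), the sodium channel gene Scn9a by 2.30 (SE 0.39) and the macrophage-derived Cd5l by 2.41 (SE 0.46). Prl8a2, a decidual prolactin relative, rose by 2.85 (SE 0.47, adjusted p = 0.00103). Tmod1, Pla2g4d and Lix1 rose by 2.61, 2.40 and 2.24. Among the falls were Elovl4, a very long chain fatty acid elongase gene (-3.29, SE 0.55), the neuronal calcium sensor gene Hpca (-2.51, SE 0.32, adjusted p = 9.17e-05), the transporter gene Slc23a3 (-2.55, SE 0.38), the prolactin relative Prl3c1 (-2.38, SE 0.44), Tuba3b (-2.99), Flrt1 (-2.70), Dmrt1 (-2.50), Nptxr (-2.37) and Gprin3 (-2.34). Tuba3b and the prolactin genes have close relatives in the genome, and how shared reads were counted is not known.

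In all, 755 of 12710 genes were called in that comparison, 402 higher and 353 lower, and 380 changed at least 2-fold, 189 up and 191 down. DESeq2 called 837 genes, 469 higher and 368 lower, and limma on log2 cRPKM with a pseudocount of 1 called 618, 273 higher and 345 lower. Each of the 4 libraries carried part of the count: 168 genes were called without DKO replicate 1, 343 without DKO replicate 2, 321 without WT replicate 1 and 395 without WT replicate 2. The 23 genes named above had the largest changes among those that passed the naming rule. Of these, Scn9a, Tuba3b, Flrt1, Dmrt1, Nptxr and Gprin3 lost their call when a library was left out, and the others kept it in each case. The rule required both libraries of a group to lie beyond both of the other, so the kept calls are partly built in.

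**Figure D2:**
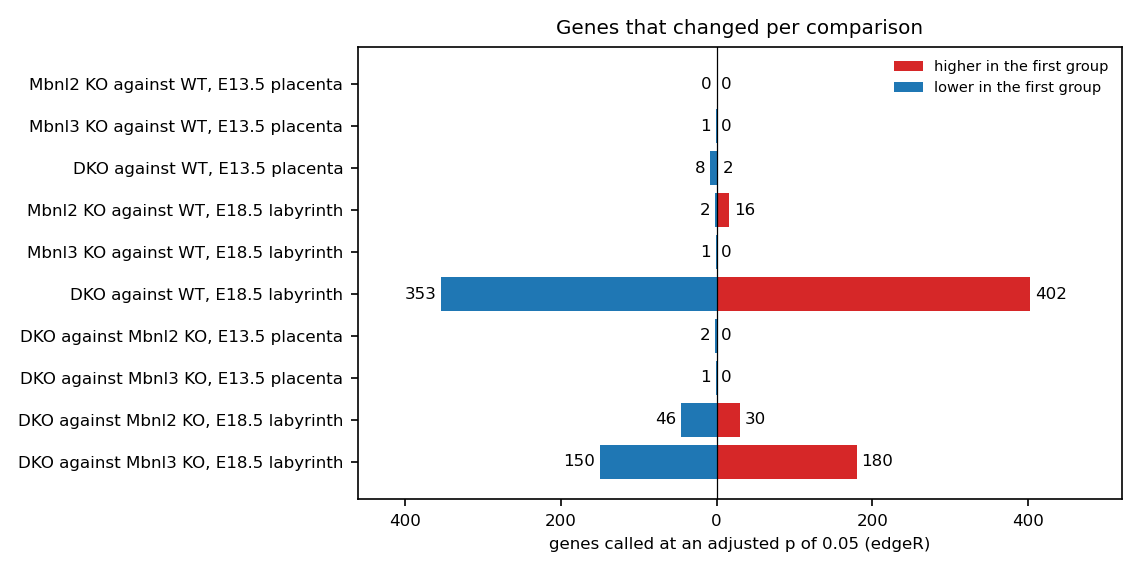
Number of genes called at an adjusted p of 0.05 (edgeR) in each genotype comparison, higher in the first group to the right in red and lower to the left in blue. The E18.5 DKO against WT had 402 higher and 353 lower, and the E13.5 Mbnl2 KO against WT had 0 of either.

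Of 9 tested markers of sinusoidal giant cells, the trophoblast giant cells that line the maternal blood spaces, 5 fell and none rose in the E18.5 DKO (median log2 change -0.61, SD 0.76 over genes; camera adjusted p = 0.000825, and 0.288 with an estimated correlation). Ctsq, a placental cathepsin (ENSMUSG00000021439, chromosome 13, 61035024 to 61040631), fell from 8960 CPM (SD 153) to 2900 CPM (SD 144), the leptin receptor gene Lepr (ENSMUSG00000057722, chromosome 4, 101717404 to 101815352) from 89.7 CPM (SD 0.491) to 20.7 CPM (SD 2.28), and Cts6 from 1750 CPM (SD 7.24) to 1060 CPM (SD 12.1), with adjusted p of 2.56e-05, 3.34e-06 and 0.0388. Besides Lepr, the called genes of this list were all placental cathepsins, Ctsm among them. That family made up 6 of the 9 markers and has close copies, and how shared reads were counted is not known. In the second syncytiotrophoblast layer, which faces the foetal vessels, 4 of 8 markers fell and none rose (median -0.58, SD 0.89; adjusted p = 0.0112, and 0.416 with an estimated correlation). They were the fusogen gene Synb (ENSMUSG00000047977, chromosome 14, 69289344 to 69294299), from 241 CPM (SD 90.0) to 53.6 CPM (SD 16.4) with adjusted p = 2.91e-05, the transcription factor gene Gcm1 (log2 change -1.66, SE 0.33, adjusted p = 0.00531), the lactate transporter gene Slc16a3 (-1.25, adjusted p = 0.0155) and Gcgr (-0.93, adjusted p = 0.0102). In the first layer 0 of 8 were called (adjusted p = 0.944).

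Genes of cholesterol synthesis were higher in the same comparison, with 18 of 20 above 0 (median 0.46, SD 0.42; camera adjusted p = 0.000825, and 0.288 with an estimated correlation). Among them Hsd17b7 rose by 1.33 (SE 0.22, adjusted p = 0.00101) and Sc5d by 0.72 (adjusted p = 0.0264), while 8 were higher and 1 lower when adjusted over the list alone. Markers of maternal decidua and uterine NK cells were higher as well (median 0.61, SD 1.04; adjusted p = 0.0194, and 0.804 with an estimated correlation), with 3 of 12 called: Prl8a2, at 15.1 CPM (SD 6.58) against 2.04 CPM (SD 0.439), the bone morphogenetic protein gene Bmp2 (log2 change 1.23, adjusted p = 0.0312) and the granzyme gene Gzmc (5.59 CPM, SD 2.02, against 1.39 CPM, SD 0.103; adjusted p = 0.0405), which has near-identical copies. With each library left out, the sinusoidal, cholesterol and decidua lists stayed called, up to adjusted p of 0.0302, 0.00607 and 0.0464, but the second syncytiotrophoblast layer reached 0.153 without WT replicate 2.

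None of the other 25 lists was called in the E18.5 DKO, though single members were. Glycogen trophoblast (camera adjusted p = 0.506) had 3 higher, the retinaldehyde dehydrogenase gene Aldh1a3 (1.94, SE 0.29, adjusted p = 0.000473), Prl7b1 (1.29) and Prl7d1 (0.93), and 1 lower, the connexin gene Gjb3 (-0.74). Parietal giant cells (0.177) had 2 higher, Prl4a1 (1.07) and Prl7a1 (1.47). Mesenchyme and pericytes (0.855) had Rgs5 (1.49, SE 0.25) and Pdgfra (0.78) higher and Acta2 (-1.03) and Col1a1 (-0.82) lower. Hypoxia and glycolysis (0.155) had Pgk1 (0.73), Ankrd37 (1.67) and Tpi1 (0.74) higher and the vasodilator gene Adm lower (-1.91, SE 0.24, adjusted p = 8.59e-05). Steroid synthesis (0.0664) had Star (0.80), Cyp17a1 (0.86) and Hsd11b2 (1.43) higher. Insulin-like growth factor signalling (0.629) had the binding proteins Igfbp2 (-1.09, SE 0.20) and Igfbp6 (-1.63, SE 0.20, adjusted p = 7.09e-05) lower. Imprinted genes (0.506) had Ascl2 higher and Slc22a18 (-1.48, SE 0.24) and Slc22a3 (-0.82) lower. Ascl2 was at 1.53 CPM (SD 0.463) against 0.359 CPM (SD 0.243). Spongiotrophoblast (0.8) had Ascl2 alone higher, nutrient transporters (0.629) Slc22a3 lower, splicing regulators (0.944) Celf2 lower (-0.92), the unfolded protein response (0.468) Herpud1 (-0.83) and Pdia4 (-0.79) lower, foetal endothelium (0.8) Sox17 higher (1.03), macrophages (0.944) Cd68 higher (1.07) and immediate early genes (0.629) Egr1 higher (0.92).

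No gene was called by edgeR's quasi-likelihood test among labyrinth progenitors (camera adjusted p = 0.564), erythroid cells (0.126), neutrophils and platelets (0.754), yolk sac endoderm (0.468), sex-linked genes (0.596), cell division (0.944), DNA replication (0.186), interferon response (0.8), oxidative phosphorylation (0.177) or polyadenylation factors (0.882). Median and mean had opposite signs for spongiotrophoblast (-0.06 and 0.10), cell division (0.08 and -0.03), interferon response (0.05 and -0.01), immediate early genes (-0.01 and 0.09) and insulin-like growth factor signalling (0.05 and -0.16), and camera pointed up for all of these but the last. The 41 called list members named here include Ctsm. Of these, 10 kept their call without each library in turn: Synb, Ctsq, Lepr, Aldh1a3, Prl8a2, Rgs5, Slc22a18, Hsd17b7, Adm and Igfbp6. The call was lost by 30 without DKO replicate 1, by 19 without DKO replicate 2, by 21 without WT replicate 1 and by 19 without WT replicate 2.

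**Figure D3:**
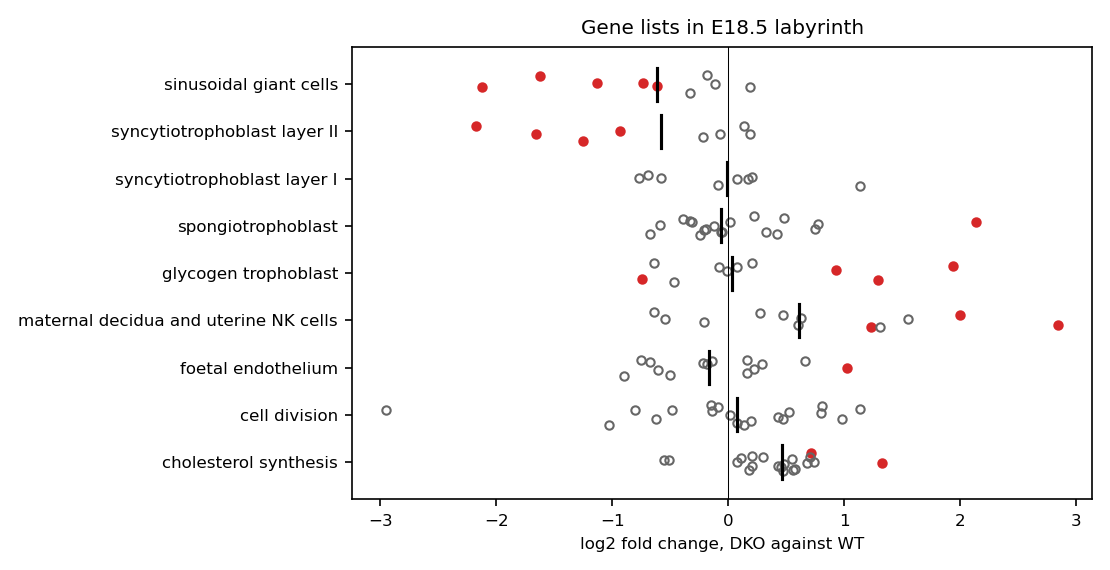
Log2 fold change of each tested gene (points) in 9 gene lists, E18.5 DKO against WT, with the list median (black bar) and called genes filled in red. The medians lie at -0.61 for sinusoidal giant cells, -0.58 for syncytiotrophoblast layer II, 0.46 for cholesterol synthesis and 0.61 for maternal decidua and uterine NK cells.

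Mbnl2 KO was compared with WT in the E18.5 labyrinth. Plac8 rose from 80.7 CPM (SD 6.49, n = 2) to 387 CPM (SD 166, n = 2), a log2 change of 2.26 (SE 0.26, adjusted p = 0.000574 by edgeR's quasi-likelihood test). The heat-sensing channel gene Trpv2 rose from 59.0 CPM (SD 0.693) to 133 CPM (SD 17.3), and the collagen-processing protease gene Bmp1 from 69.1 CPM (SD 10.4) to 149 CPM (SD 2.6), with adjusted p of 0.00263 and 0.0158. Further rises were those of Kcnj5 (2.42, SE 0.37), Sult1e1 (2.33, SE 0.32), Esrrb (1.86, SE 0.36), Pou2f3 (1.79, SE 0.31), Drd4 (1.77, SE 0.27), the netrin receptor gene Unc5a (1.57, SE 0.30), Prl2c3 (1.56, SE 0.27), Pxdc1 (1.37) and Spn (1.05). The pyruvate carboxylase gene Pcx fell from 107 CPM (SD 14.0) to 45.3 CPM (SD 12.5) and Lepr from 89.7 CPM (SD 0.491) to 42.1 CPM (SD 8.58), with adjusted p of 0.0191 and 0.0171. In total 18 genes were called, 16 higher and 2 lower. Without Mbnl2 KO replicate 1 only 1 gene was called, Plac8 (log2 change 1.74, adjusted p = 0.0147), against 252 without replicate 2, 9 without WT replicate 1 and 7 without WT replicate 2. Of the 14 genes just named, 1 kept its call without Mbnl2 KO replicate 1, 13 without Mbnl2 KO replicate 2, 4 without WT replicate 1 and 3 without WT replicate 2. Mbnl2 KO replicate 1 exceeded replicate 2 by a median log2 of 0.61 (SD 0.29) over the spongiotrophoblast markers, with 18 of 19 higher, and the endothelial markers differed by -0.50 (SD 0.44).

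Camera called 4 lists in the E18.5 Mbnl2 KO: lower sinusoidal giant cells (median -0.30, SD 0.49, adjusted p = 0.0329), higher mesenchyme and pericytes (0.52, SD 0.36, 0.0242), higher cell division (0.39, SD 0.66, 0.0242) and higher immediate early genes (0.27, SD 0.47, 0.0242). None was called with an estimated correlation (adjusted p = 0.561, 0.561, 0.592 and 0.52). Among these genes only Lepr was called over all genes, and when adjusted over the list alone Ctsm joined it among the sinusoidal markers. Adjusted in the same way, 2 mesenchyme and pericyte markers were called higher. The list calls were lost without Mbnl2 KO replicate 2 (0.54, 0.0703, 0.231 and 0.0895) and without WT replicate 1 (0.23, 0.291, 0.0519 and 0.0998).

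In the Mbnl3 KO labyrinth at E18.5, Mbnl3 was the only gene called by edgeR's quasi-likelihood test, with 504 genes at an unadjusted p under 0.05, where 636 were expected by chance. The next smallest p-values, given as values, were those of the zinc transporter gene Slc39a2 (2.67 CPM, SD 0.0985, against 8.52 CPM, SD 0.0336; adjusted p = 0.22), the kinase gene Hipk2 (18.9 CPM, SD 2.24, against 42.1 CPM, SD 6.39; 0.22), Pcsk6 (log2 change 1.27, SE 0.26; 0.347) and Hspa12a (-1.65, SE 0.36; 0.53). Spongiotrophoblast markers were higher as a list (median 0.40, SD 0.22, 18 of 19 above 0, camera adjusted p = 0.000212), yolk sac endoderm lower (-0.62, SD 0.54, 0.000212) and hypoxia and glycolysis higher (0.23, SD 0.26, 0.0149), with 0.752, 0.71 and 0.71 with an estimated correlation. The spongiotrophoblast call was lost without Mbnl3 KO replicate 2 (0.124) and WT replicate 2 (0.343), the yolk sac call without Mbnl3 KO replicate 1 (0.062), and the hypoxia call without Mbnl3 KO replicate 1 (0.207), Mbnl3 KO replicate 2 (0.0995) and WT replicate 1 (0.492).

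DKO was then compared with each KO in the E18.5 labyrinth, to measure how the label DKO differed from each single one. Against Mbnl3 KO, Mbnl2 itself had a log2 change of 0.04 (SE 0.20). Trpv2 (ENSMUSG00000018507, chromosome 11, 62574486 to 62600515) rose from 55.9 CPM (SD 7.9) to 225 CPM (SD 8.48), with adjusted p = 1.79e-06 by edgeR's quasi-likelihood test. Drd4 rose by a log2 of 3.17 (SE 0.27, adjusted p = 2.16e-06). Rises also came from Prl8a2 (3.48, SE 0.57), Lix1 (3.0, SE 0.50), Esrrb (2.87, SE 0.40), Nat8l (2.44), Tmod1 (2.38), the immunoglobulin superfamily gene Prtg (2.37, SE 0.29), Gna14 (2.22), Sult1e1 (2.19), Aldh1a3 (2.15) and the prostaglandin receptor gene Ptger4 (1.98). Corin (-3.14, SE 0.41, adjusted p = 0.000209), Tuba3b (-3.03), Dmrt1 (-2.82), Flrt1 (-2.68), Ano7 (-2.68), Hpca (-2.53), Tnnc1 (-2.51), Prl3c1 (-2.38), Il21r (-2.36), Fanci (-2.11), Kcnj12 (-2.10) and Tmem141 (-2.04) fell. In all 330 genes were called, 180 higher and 150 lower, against 75 without DKO replicate 1, 146 without DKO replicate 2 and 85 without Mbnl3 KO replicate 2. Of the 24 genes just named, the 11 that kept their call without each library in turn were Prl8a2, Drd4, Lix1, Esrrb, Nat8l, Prtg, Sult1e1, Aldh1a3, Trpv2, Corin and Hpca, and 12 kept it without DKO replicate 1, 17 without DKO replicate 2, 23 without Mbnl3 KO replicate 1 and 18 without Mbnl3 KO replicate 2.

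In DKO against Mbnl2 KO, Synb fell from 210 CPM (SD 6.22) to 53.6 CPM (SD 16.4), a log2 change of -1.97 (SE 0.24, adjusted p = 0.000806 by edgeR's quasi-likelihood test), and Tnnc1 fell from 13.1 CPM (SD 3.01) to 1.7 CPM (SD 1.19). Slc39a2 (-2.00, SE 0.31), Etd (-2.00), Corin (-2.33), Flrt1 (-2.62), Prl3c1 (-1.98), Adamtsl1 (-1.85), Slc23a3 (-1.85), Hpca (-1.81) and Tex14 (-1.71) fell as well. Drd4 rose from 11.4 CPM (SD 1.68) to 35.1 CPM (SD 0.941), with adjusted p = 0.00194, and so did Cd5l (2.81, SE 0.48), Cyfip2 (1.54), Sgsm1 (1.54), Nat8l (1.47), Meltf (1.40), Syt13 (1.36), Krt25 (1.33), the tight junction gene Cldn3 (1.31), Rpusd3 (1.30), Pcsk6 (1.22) and Tnnt1 (1.17). The count was 76, 30 higher and 46 lower, against 3 without DKO replicate 1, 23 without DKO replicate 2 and 16 without Mbnl2 KO replicate 1. Only Drd4 of the 23 genes kept its call without each library in turn, with 2 called without DKO replicate 1, 12 without DKO replicate 2, 8 without Mbnl2 KO replicate 1 and 12 without Mbnl2 KO replicate 2.

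The departure from additivity asks whether the DKO differs from the sum of both single KO effects. By edgeR's quasi-likelihood test 0 genes were called at E18.5, with 501 at an unadjusted p under 0.05, and DESeq2 called 0 and limma 2 (pseudocount 1) or 1 (pseudocount 0.1). The smallest p-values at E18.5 included those of Hpca (-1.83, SE 0.42), Corin (-2.12, SE 0.53) and the protease inhibitor gene Wfdc2 (-1.42, SE 0.36), each at an adjusted p of 1. At E13.5 edgeR, DESeq2 and limma called 0 genes, with 441 at an unadjusted p under 0.05 by edgeR, and the perforin gene Prf1 had -1.98 (SE 0.46, adjusted p = 0.999).

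Mbnl2 KO against WT was set beside DKO against Mbnl3 KO, which share no library, and Mbnl3 loss in the same way. At E18.5 all 18 genes called in Mbnl2 KO against WT had the same sign in DKO against Mbnl3 KO, and 16 were called higher and 2 lower in both, where 0.23 and 0.02 were expected by chance. Of the 330 genes called in DKO against Mbnl3 KO, 319 (96.7%) had the same sign in Mbnl2 KO against WT, compared with 69.1% of all 12709 genes. Across genes, which are not independent replicates, Pearson's r was 0.366 and Spearman's rho 0.469, and r fell to 0.216 without Mbnl3 KO replicate 2. For Mbnl3 loss at E18.5, r was 0.177 (rho 0.235), 0.109 without Mbnl3 KO replicate 2, 0.109 without WT replicate 2 and 0.112 without Mbnl2 KO replicate 2, and 69 of 75 genes (92%) shared the sign, compared with 59.5% of all genes. At E13.5 Mbnl2 counts were not called different between DKO and Mbnl3 KO (log2 change 0.60, SE 0.20, adjusted p = 0.789). There r was -0.002 for the Mbnl2 labels and 0.061 for the Mbnl3 labels, within a range of -0.014 to 0.023 and -0.002 to 0.102 when each library was left out. Against their common WT, the E18.5 Mbnl2 KO and DKO effects had a covariance of 0.1397, where simulated data without a genotype effect gave 0.0507. The other E18.5 and E13.5 pairs with shared controls exceeded their simulated covariance by at most 0.0254. Some lay below it, as did E13.5 Mbnl2 KO with DKO (0.0509 against 0.0582). The simulation used a pooled spread, while WT replicates differed by a chi-square per gene of 2.76 at E13.5 and 18.82 at E18.5. Its covariance may therefore not match that of the WT libraries, so it neither excludes shared effects nor gives the size of an excess. Mbnl2 KO against WT and DKO against Mbnl3 KO at E18.5, without a shared library, had a covariance of 0.1115.

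**Figure D4:**
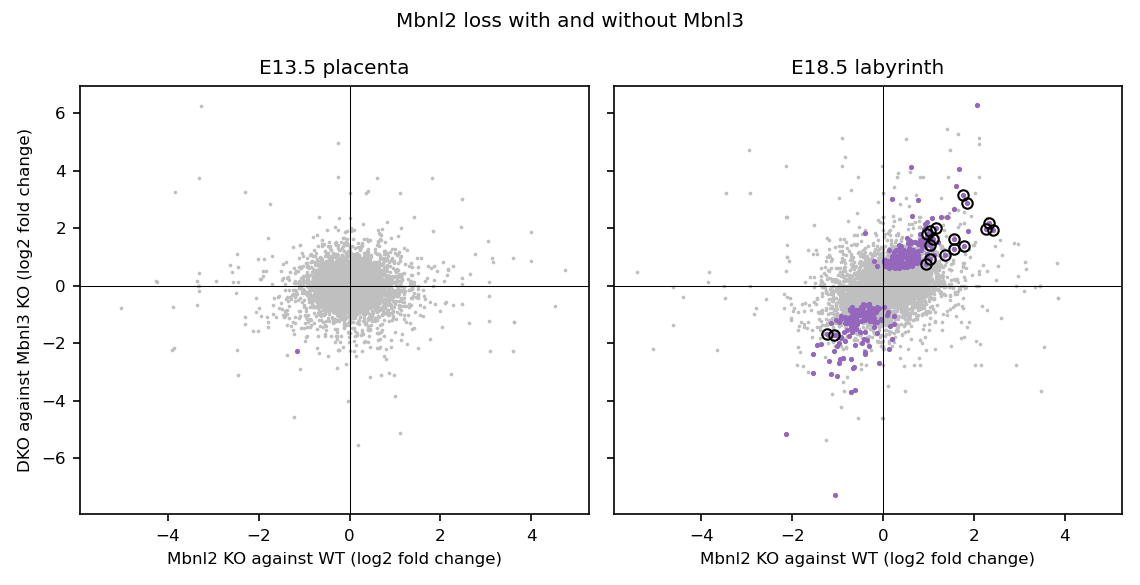
Log2 fold change of each gene (12709 points) in Mbnl2 KO against WT (horizontal) and in DKO against Mbnl3 KO (vertical), with genes called in the latter in purple and genes called in the former circled. In the E18.5 labyrinth 319 of 330 purple genes share the sign, while r is -0.002 in the E13.5 placenta.

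At E13.5 the same comparisons were made in the whole foetal placenta. In DKO against WT, Cts6 (ENSMUSG00000021441, chromosome 13, 61195132 to 61203410) fell from 13.8 CPM (SD 0.451, n = 2) to 1.77 CPM (SD 0.317, n = 2), a log2 change of -2.90 (SE 0.33, adjusted p = 0.000182 by edgeR's quasi-likelihood test). Its neighbour Ctsq fell from 542 CPM (SD 36.9) to 205 CPM (SD 4.66), and the irisin precursor gene Fndc5 (ENSMUSG00000001334, chromosome 4, 129136999 to 129144593) from 23.0 CPM (SD 0.0738) to 6.07 CPM (SD 1.11), with adjusted p of 0.000893 and 0.000267. Prl3c1 (-2.34, SE 0.42), the transcriptional repressor gene Bcl6 (-2.26, SE 0.40), Creb3l1 (-1.33, SE 0.23) and the cathepsin gene Ctsh (-1.27, SE 0.23) also fell. The prostaglandin transporter gene Slco2a1 rose from 151 CPM (SD 6.07) to 318 CPM (SD 82.8) and Bmp1 from 46.1 CPM (SD 1.74) to 95.8 CPM (SD 26.9), both with adjusted p = 0.0334. Sinusoidal giant cell markers were lower as a list (9 genes, all below 0, median -0.64, SD 0.89; camera adjusted p = 9.53e-09, and 0.0595 with an estimated correlation), with 2 called over all genes and 6 when adjusted over the list alone. Its call stayed without each library, up to an adjusted p of 0.000212. In total 10 genes were called, 2 higher and 8 lower, against 30 without DKO replicate 1 (24 higher and 6 lower), 7 without DKO replicate 2, 4 without WT replicate 1 and 4 without WT replicate 2. Beside Mbnl3, only Cts6, Fndc5 and Ctsq kept their call in each case. Of the 9 genes just named, 6 kept it without DKO replicate 1, 4 without DKO replicate 2, 3 without WT replicate 1 and 3 without WT replicate 2.

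In the E13.5 Mbnl2 KO, 0 genes were called by edgeR's quasi-likelihood test, and 203 had an unadjusted p under 0.05 where 636 were expected by chance. DESeq2 and limma also called 0, but each of these methods pools the spread over the groups. Replicates of E13.5 WT and Mbnl2 KO differed least, with a chi-square per gene of 2.76 and 5.91 against 24.03 in E13.5 DKO. The pooled spread may be too wide for this comparison, so 0 calls do not show that an effect was absent. The smallest p-values, all with an adjusted p of 1, were those of Cts6 (6.15 CPM, SD 0.387, against 13.8 CPM, SD 0.451), the cytokine signalling suppressor gene Socs5 (18.1 CPM, SD 3.29, against 7.94 CPM, SD 2.52), Ahsg (4.9 CPM, SD 0.242, against 1.05 CPM, SD 0.402), Ak1 and Cyba. Without Mbnl2 KO replicate 1, 1 gene was called. Sinusoidal giant cell markers were lower as a list (median -0.30, SD 0.32, camera adjusted p = 1.26e-06), and yolk sac endoderm (0.88, SD 1.07, 2.21e-09), mesenchyme and pericytes (0.28, SD 0.25, 0.0182) and erythroid cells (0.27, SD 0.09, 0.0318) were higher, with 0.148, 0.329, 0.627 and 0.627 with an estimated correlation. The erythroid call was lost without Mbnl2 KO replicate 1 (0.419), WT replicate 1 (0.157) and WT replicate 2 (0.13), and the mesenchyme call without Mbnl2 KO replicate 2 (0.426) and WT replicate 1 (0.183).

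In the E13.5 Mbnl3 KO only Mbnl3 was called by edgeR, with 490 genes at an unadjusted p under 0.05, and 3 genes were called without Mbnl3 KO replicate 1. The next smallest p-values (adjusted p = 0.996) were those of the glucose transporter gene Slc2a3 (81.9 CPM, SD 5.55, against 42.5 CPM, SD 1.09), Fndc5 (12.7 CPM, SD 2.8, against 23.0 CPM, SD 0.0738), Wfdc2 (421 CPM, SD 67.2, against 244 CPM, SD 19.1) and Spred2 (4.66 CPM, SD 0.128, against 9.27 CPM, SD 0.217). All 19 genes of oxidative phosphorylation were above 0 (median 0.25, SD 0.10, camera adjusted p = 0.000103, and 0.664 with an estimated correlation). Sinusoidal giant cell markers were lower (median -0.15, SD 0.27, 0.034, and 0.664 with an estimated correlation), a call lost without Mbnl3 KO replicate 1 (0.14) and WT replicate 2 (0.366). DKO against Mbnl2 KO at E13.5 called Mbnl3 and Fndc5 (-1.57, SE 0.23, adjusted p = 0.0107), and Fndc5 lost its call without DKO replicate 1 or either Mbnl2 KO replicate. That comparison gave 10 calls without DKO replicate 1, 6 without DKO replicate 2 and 1 without either Mbnl2 KO replicate. DKO against Mbnl3 KO called Cts6 alone (-2.28, SE 0.33, adjusted p = 0.0184), a call that remained only without Mbnl3 KO replicate 1, where the count was 2. It was 17 without DKO replicate 1, 0 without DKO replicate 2 and 1 without Mbnl3 KO replicate 2.

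Whether each genotype's effect differed between E18.5 labyrinth and E13.5 placenta was tested directly. For DKO, Drd4 changed by 2.89 more at E18.5 on the log2 scale (SE 0.34, adjusted p = 0.000423 by edgeR's quasi-likelihood test), Plac8 by 2.68 (SE 0.36, adjusted p = 0.00169), the secreted Wnt antagonist gene Sfrp5 by 3.41 (SE 0.51), Prl8a2 by 3.11 (SE 0.57) and Gzmc by 3.05 (SE 0.66). Tnnc1 (-3.97, SE 0.66), Etd (-3.00, SE 0.53), Olfml3 (-2.70, SE 0.56), Endou (-2.62, SE 0.51) and Cpne8 (-2.39, SE 0.54) differed the other way. In all 72 genes were called, 46 with a higher effect at E18.5 and 26 with a lower effect. The count was 10 without E18.5 DKO replicate 1 (9 higher and 1 lower), 39 without E18.5 DKO replicate 2, 34 without E18.5 WT replicate 2, 275 without E13.5 DKO replicate 1 (121 higher and 154 lower), 39 without E13.5 DKO replicate 2, 11 without E13.5 WT replicate 1 and 25 without E13.5 WT replicate 2. Of these 10 genes, only Sfrp5, Drd4 and Plac8 kept their call without each of the 8 libraries. For Mbnl2 loss Plac8 alone was called (2.50, SE 0.36, adjusted p = 0.0133), a call lost without 7 of the 8 libraries, and 11 genes were called without E18.5 Mbnl2 KO replicate 2. For Mbnl3 loss 0 genes were called by edgeR, DESeq2 or limma, with 314 at an unadjusted p under 0.05 by edgeR. Across genes the DKO effects in both tissues had r = 0.102, and 492 of the 754 genes called at E18.5 (65.3%) had the same sign at E13.5, compared with 51.2% of all genes.

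WT labyrinth at E18.5 against WT placenta at E13.5 gives the scale of the change between the tissues, in which stage and dissection differ together. Cts6 rose from 13.8 CPM (SD 0.451, n = 2) to 1750 CPM (SD 7.24, n = 2), a log2 change of 6.99 (SE 0.27, adjusted p = 1.1e-12 by edgeR's quasi-likelihood test), and Ctsq from 542 CPM (SD 36.9) to 8960 CPM (SD 153). Psca, Igfbp6 and Prl3a1 rose by 6.24 (SE 0.39), 5.87 (SE 0.30) and 6.87 (SE 0.46). The embryonic globin gene Hbb-y fell from 12000 CPM (SD 162) to 7.4 CPM (SD 7.46) while the adult Hbb-bs rose from 3270 CPM (SD 349) to 12200 CPM (SD 806). The thyroid hormone deiodinase gene Dio3 fell from 288 CPM (SD 14.6) to 0.954 CPM (SD 0.154), and Prl8a2 from 567 CPM (SD 36.5) to 2.04 CPM (SD 0.439). Aldh1a3 (-5.09, SE 0.26), Htra3 (-4.65, SE 0.33), Hsd17b7 (-4.82, SE 0.21), the mitotic genes Top2a (-3.32), Ccnb1 (-3.36) and Plk1 (-3.47), and Tpbpa (-1.49, SE 0.30) fell. The glucose transporter gene Slc2a1 (1.47), the phosphate transporter gene Slc20a1 (1.89), Afp (2.63) and Igfbp2 (1.69) rose. In all 4777 genes were called, 2441 higher and 2336 lower, and 3137 and 3084 without E13.5 WT replicates 1 and 2.

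Camera called 11 lists between the stages in WT. Higher at E18.5 were sinusoidal giant cells (median 1.31, SD 2.60, adjusted p = 0.00203), yolk sac endoderm (2.03, SD 0.81, 1.52e-05), nutrient transporters (1.00, SD 0.73, 0.00193), foetal endothelium (0.75, SD 0.91, 0.0228) and insulin-like growth factor signalling (1.02, SD 1.72, 0.00503). Lower were cell division (-2.79, SD 0.90, 1.67e-14), DNA replication (-1.71, SD 0.86, 6.5e-10), cholesterol synthesis (-0.81, SD 1.03, 1.19e-05), maternal decidua and uterine NK cells (-3.69, SD 2.67, 1.19e-05), glycogen trophoblast (-0.86, SD 2.19, 0.00503) and oxidative phosphorylation (-0.40, SD 0.25, 0.0166). With an estimated correlation only DNA replication was called (adjusted p = 0.0027). The endothelial call was lost without E18.5 WT replicate 2 (0.0823) and the oxidative phosphorylation call without E13.5 WT replicate 2 (0.0548). Median and mean had opposite signs for spongiotrophoblast (-0.24 and 0.02), erythroid cells (0.50 and -2.45) and neutrophils and platelets (-0.28 and 0.28), none of them called.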

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

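The differences between tissues in this part were planned, while the tests of explanations for the patterns below were all chosen after the result was seen.

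The DKO effect differed between E18.5 labyrinth and E13.5 placenta for 72 genes by edgeR's quasi-likelihood test of the difference, and these were singled out because the same genotype contrast gave unlike effects in the tissues. The effect was higher at E18.5 by a log2 of 3.41 for Sfrp5, 3.11 for Prl8a2, 3.05 for Gzmc, 2.89 for Drd4 and 2.68 for Plac8. It was lower for Tnnc1 (-3.97), Etd (-3.00), Olfml3 (-2.70), Endou (-2.62) and Cpne8 (-2.39). Mbnl2 loss gave 1 such gene, Plac8 (2.50, adjusted p = 0.0133). For DKO the number of genes called fell with most libraries left out and rose without E13.5 DKO replicate 1, by the counts given above. Leaving out a library leaves a lone library in its group and also changes the pooled spread. Those counts therefore show that the number is unstable, but not which library the differences rest on. Plac8 lost its call for Mbnl2 loss without any library but E18.5 Mbnl2 KO replicate 2. Tissue and stage differ together, so either may lie behind these 72 and 1 genes, and no value separates them. Tissue carried into the DKO labyrinth samples, weighed next, is not excluded for these genes either.

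Changes in the E18.5 DKO ran against the change between stages: over the 754 genes called besides Mbnl3, the log2 change correlated at r = -0.586 with the change from E13.5 to E18.5 in the Mbnl3 KO groups, which share no library with it, against -0.246 over all genes, and 204 of 402 risers (50.7%, against 17.2% of all genes) and 196 of 352 fallers (55.7%, against 17.9%) had been called the other way between stages. Across the 4450 genes called between the stages in Mbnl3 KO, besides Mbnl3 and the cell division list, r was -0.353. That value uses the same contrasts as the pattern itself, so it is no separate test of a delay. A delay of part of the stage-related change is a candidate explanation that remains open. A delay of all of it cannot be told apart from a partial one, since the slope of those genes predicted 0.35 for cell division, which had a median of 0.08 (SD 0.92). Spongiotrophoblast carried into the DKO samples cannot be told apart from a change in the labyrinth, since its 19 markers had a median of -0.06 (SD 0.64), but their level in WT labyrinth was already 0.85 times that at E13.5 (median), and Tpbpa had 19900 and 12500 CPM in DKO against 12300 and 6950 CPM in WT. The same holds for maternal decidua and the decidual genes. A share of 2.31% of the E13.5 placenta level, set by Prl8a2, would cover the larger part of the rise for only 3 of the risers (0.7%). But that level is of placenta and not of decidua alone, and the decidual list was higher by a median of 0.61 (SD 1.04).

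The E18.5 Mbnl2 KO gene calls rested largely on replicate 1, by the counts given above with each replicate left out. Leaving out either replicate also takes the spread between them out of the pooled estimate. The gene list calls went the other way: they stayed without replicate 1 and were lost without replicate 2. A tissue mix of replicate 1 alone was argued against by replicate 2, which had the same sign as DKO against Mbnl3 KO for 94.2% of its 330 called genes, where WT replicate 1 against WT replicate 2 gave 53.3%. A WT sample labelled as replicate 2 was argued against by a median log2 change of 0.47 (SD 0.38) in that direction, where WT gave 0.03 (SD 0.42), a narrow margin. Replicate 1 exceeded replicate 2 in 18 of 19 spongiotrophoblast markers (median 0.61, SD 0.29), so a difference in dissection may add to the number of calls. The replicates also differed in Xist (149 and 96.7 CPM) and Ddx3y (11.9 and 30.6 CPM), so a different share of female and male tissue stays open, untested, beside Mbnl2 loss itself.

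Mbnl2 counts were not called lower in the libraries labelled Mbnl2 KO or DKO. Loss of Mbnl3 alone in the E18.5 DKO samples was examined over the 18 genes called in Mbnl2 KO against WT. Each DKO library differed from each Mbnl3 KO library in that direction by a median log2 of at least 1.54 (SD 0.57). Between the Mbnl3 KO replicates the median was 0.38 (SD 0.28). These values argue against DKO samples that carry the Mbnl3 KO changes alone. They do not exclude a tissue mix shared with Mbnl2 KO while Mbnl2 was intact. The 18 calls rested largely on Mbnl2 KO replicate 1. In DKO against Mbnl3 KO 330 genes were called, 75 without DKO replicate 1 and 85 without Mbnl3 KO replicate 2. At E13.5 DKO against Mbnl3 KO called 1 gene and Mbnl2 KO against WT called 0. A sample that kept an intact Mbnl2 cannot be told apart there from a loss whose effects were few or too small to call. The gene called was Cts6, which was also lower, though not called, in Mbnl2 KO against WT. Sinusoidal giant cell markers, Cts6 among them, were lower there as a list (9 of 9 below 0, camera adjusted p = 1.26e-06, and 0.148 with an estimated correlation). The list was also lower in E13.5 Mbnl3 KO (8 of 9 below 0, camera adjusted p = 0.034, and 0.664 with an estimated correlation). Both falls are measured against the same WT libraries, so they are not independent and do not single out the Mbnl2 label. Across genes, Mbnl2 KO against WT and DKO against Mbnl3 KO at E13.5 had r = -0.002. A counted 3' end that lies outside the deleted part is a candidate explanation that remains open, with a log2 change of 0.04 (SE 0.20) for Mbnl2 in E18.5 DKO against Mbnl3 KO.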

How the results depend on the processing

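Leaving out libraries for the gene lists and leaving out E18.5 Mbnl2 KO replicate 1 from comparisons that do not use it were added after the data were seen, as was the count of families under RLE. Among named genes called in the main test, 279 calls stayed and 1 was lost under RLE, 275 and 3 with a minimum of 5 CPM, 280 and 0 without a filter, 265 and 15 with a replicate block, 112 and 28 with a fit per tissue, 262 and 3 by DESeq2, 245 and 35 by limma with a pseudocount of 1, 228 and 52 with 0.1, and 951 and 302 over all libraries left out. None of 3469 called values changed sign, and 71 of 4629 uncalled ones did, the largest of 1.2 in the main test. All settings reuse the same counts, so a kept sign is no separate evidence for the direction of a change. Counts of genes stayed within 1.5 times under RLE and under a minimum of 5 CPM in every comparison. The replicate numbers do not pair the groups, as same-number replicates correlated at -0.14 to 0.17.

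Without a low-count filter, which tests more genes, E13.5 calls became 7 (Mbnl2 KO), 12 (Mbnl3 KO), 74 (DKO), 41 (DKO against Mbnl2 KO), 57 (DKO against Mbnl3 KO) and 11 (additivity), E18.5 calls 345, 14, 1169 (722 shared with the main test), 296, 708 and 13, and tissue differences 54 (Mbnl2), 5 (Mbnl3) and 345 (DKO). A replicate block gave 6 for E13.5 DKO and 28 for E18.5 Mbnl2 KO. A fit per tissue gave 11 for E18.5 Mbnl2 KO, 0 for E13.5 DKO against Mbnl3 KO and 25 for E18.5 DKO against Mbnl2 KO. Limma with a pseudocount of 1 gave 5 for E13.5 DKO, 9 and 2 for E18.5 Mbnl2 KO and Mbnl3 KO, 2 for E13.5 DKO against Mbnl3 KO, 2 for E18.5 additivity and 0 for the tissue difference of Mbnl2. With 0.1 it gave 5, 2 and 476 for E18.5 Mbnl2 KO, Mbnl3 KO and DKO, 16 for E18.5 DKO against Mbnl2 KO, 1 for E18.5 additivity and 0 for the tissue difference of Mbnl2. DESeq2 gave 19 for E13.5 DKO, 81 for E18.5 Mbnl2 KO, 6 and 16 for E13.5 DKO against Mbnl2 KO and Mbnl3 KO, 119 for E18.5 DKO against Mbnl2 KO, and 3 and 145 for the tissue differences of Mbnl2 and DKO. Apart from the number of genes tested, the cause was not tested.

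With each library left out in turn, which leaves fewer samples, calls ranged from 0 to 1 (E13.5 Mbnl2 KO), 1 to 3 (E13.5 Mbnl3 KO), 4 to 30 (E13.5 DKO), 1 to 252 (E18.5 Mbnl2 KO) and 168 to 395 (E18.5 DKO), which was 839 without the unused Mbnl2 KO replicate 1. For DKO against Mbnl2 KO they ranged from 1 to 10 at E13.5 and 3 to 57 at E18.5, for DKO against Mbnl3 KO from 0 to 17 and 75 to 266, with 372 without the unused Mbnl2 KO replicate 1. Tissue differences ranged from 0 to 11 (Mbnl2) and 10 to 275 (DKO), and WT stages from 3084 to 3966.

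Of the gene lists called by camera, 0 remained called with an estimated correlation in each genotype comparison and 1 of 11 in the WT stages. Fry called 0 for either single KO in either tissue, 7 for E18.5 DKO and 23 for the WT stages, and a replicate block gave 7 for E13.5 Mbnl2 KO and 2 for E13.5 DKO. With a library left out, list counts ranged from 2 to 6 (E13.5 Mbnl2 KO), 1 to 4 (E13.5 Mbnl3 KO), 1 to 4 (E13.5 DKO), 0 to 5 (E18.5 Mbnl2 KO), 1 to 3 (E18.5 Mbnl3 KO) and 5 to 6 (E18.5 DKO).

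Correlations across genes with a minimum of 5 CPM were -0.007 for Mbnl2 loss with and without Mbnl3 at E13.5, 0.553 at E18.5, 0.274 for Mbnl3 loss at E18.5 and 0.163 for Mbnl3 KO in both tissues. Over genes called in a single comparison of the pair, without those called in both, they were 0.874 and 0.762 for Mbnl2 and Mbnl3 loss at E18.5. They were 0.413 for Mbnl2 KO in both tissues and 0.245 for DKO in both. Choosing called genes leaves out small changes, which can raise r by itself, so these values do not show closer agreement than those over all genes. With a library left out, correlations over all genes ranged from -0.014 to 0.023 and -0.002 to 0.102 (Mbnl2 and Mbnl3 loss, E13.5), 0.216 to 0.392 and 0.109 to 0.188 (E18.5), -0.011 to 0.051 (Mbnl2 KO in both tissues), 0.043 to 0.109 (Mbnl3 KO) and 0.033 to 0.167 (DKO). Depth limits values near the floor of 0.288 to 0.611 CPM, and genes under the filter's minimum count of 10 were not tested.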

Other observations

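The counts in this part are of gene families and neighbouring genes that were chosen after their values were seen.

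The prolactin family, a cluster of placental hormones on chromosome 13, had 21 tested genes. In E18.5 DKO against WT 9 were called higher (Prl4a1, Prl7a1, Prl8a2, Prl7b1, Prl7d1, Prl2a1, Prl2c3, Prl7c1 and Prl2c1) and 1 lower (Prl3c1), with a median log2 change of 0.33 (SD 1.20 over genes). Between the stages in WT 14 were lower and 4 higher at E18.5 (median -1.62, SD 3.35). Of 6 placental cathepsins, 4 were lower in E18.5 DKO (Ctsq, Cts6, Ctsj and Ctsm, family median -0.67, SD 0.53) and 2 in E13.5 DKO (Ctsq and Cts6, median -0.70, SD 0.98). All 6 are also on the sinusoidal giant cell list, so these counts are not separate from that list. Of 21 serpins, 5 were higher in E18.5 DKO (Serpinb9c, Serpini1, Serpine1, Serpinb6b and Serpinb9g) and 1 lower (Serpine2). Of 12 pregnancy-specific glycoproteins 0 were called by edgeR in either DKO comparison (medians -0.08 and 0.28). The same counts were found under RLE scaling. Many of these genes have close copies, and how reads shared between copies were counted is not known.

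Within 10 Mb of Mbnl2, 4 of 21 tested genes were called in E18.5 DKO against WT (Ubac2, Rap2a, Gpc6 and B930095G15Rik), compared with 751 of 12688 other genes (Fisher's exact test, two-sided, p = 0.0329, adjusted p = 0.0658 over the pair of loci). Within 10 Mb of Mbnl3, 2 of 45 were called (Etd and 1600025M17Rik, Fisher's exact p = 1). At E13.5 none was called near either locus.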
